A study of Arabidopsis thaliana with 18 samples.

How the data were processed

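Gene expression was measured in whole Arabidopsis thaliana seedlings grown for 10 days on agar plates under continuous light. Wild-type Columbia plants (WT) and the mutants elf3-7 and tfl1-1 were each grown at 16 °C and at 23 °C. Each of the 6 combinations of genotype and temperature had 3 biological replicates, lettered A, B and C, for which the labels state independent RNA preparations, so 18 arrays were compared. Total RNA had been labelled with biotin and hybridised to an Affymetrix Arabidopsis array.

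The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes; the version and the annotation used are not given in the sources used here. The table held 22810 probe sets with no missing value. Values ran from 2.33 to 14.08, and the median of an array lay between 5.49 and 5.62. RMA had already put the arrays on a common scale, and no further normalization was applied. The arrays carry no read depth, so precision is limited by the number of arrays. A log2 difference of RMA values tends to understate the change of dim transcripts.

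The 64 control probe sets were left out of the tests, which left 22746 probe sets. Probe sets were named from the platform annotation, updated through gene identifiers in the RefSeq gene table of TAIR10.1, which was used for names only. A single gene was named for 13513 probe sets, of which 13436 were matched by Entrez identifier, and these cover 13355 genes. Of these probe sets, 1580 carry a gene symbol and 11933 a locus code only. Another 503 probe sets name several genes, and 8730 (38.4%) are unnamed here. No probe set was named here as ELF3 or TFL1, so the genotype labels could not be checked against the mutated genes. Of the 22 flowering, light and clock genes chosen to be reported in any case, only GI is named here. Where several probe sets named a gene, the brightest over all arrays was used.

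Each probe set was fitted with limma 3.58.1 in R 4.3.3, as a model of the 6 group means over all 18 arrays followed by empirical Bayes moderation, and all tests were two-sided. The 9 comparisons were 23 °C minus 16 °C in each genotype, each mutant minus WT at each temperature, and the difference between each mutant and WT in the 23 °C minus 16 °C response. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. Differences are given on the log2 scale with the standard error (SE) of the fit, with 3 arrays in each group. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

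The design, the comparisons, 18 gene lists with 262 genes, most of the alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names up to 10 higher and 10 lower genes per pairwise comparison, those with the largest difference among called probe sets that name 1 gene with a symbol and whose 3 and 3 arrays do not overlap. It also names up to 4 called members of each fixed list, or up to 2 members as values where none was called. A symbol was read, after the annotation was seen, as any name other than a bare locus code. The loci AT1G43590, AT5G44520, AT1G73480 and AT4G28080, and members of the added lists below, were named after their values were seen.

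Only 39 of the 262 list genes are named here. The 8 lists with at least 3 measured members were tested with camera in limma, at a preset correlation between genes of 0.01, with adjustment over the lists of each comparison: floral promotion, floral repression, gibberellin, growth (shade and auxin), heat shock, cold response, flavonoid and anthocyanin, and root markers. The test was repeated with the correlation estimated for each list. The gibberellin list held only the receptor genes GID1A, GID1B and GID1C, and floral repression only ATC, SMZ and SNZ. The growth list held only YUC2, IAA29 and EXPA8, and heat shock only AT5G48570, AT1G53540 and ATHSP22.0. Tests of these lists speak for those members, not for a whole pathway. A further 20 gene families were picked from the annotation after the first results had been seen. They were tested in the same way, adjusted over those 20, and describe patterns noticed in the same data.

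The control probe sets were searched for batches. The 24 probe sets for spiked Bacillus transcripts were bright in the 6 replicate C arrays and dim in the 12 replicate A and B arrays, and replicate C was treated as a labelling batch from then on. Each result was recomputed with this batch as a block and within replicates A and B alone. Replicate C holds 1 array per group, so it gives differences without a test. The labels do not say that a letter marks a shared day. The deviations of same-lettered arrays from their group means were therefore correlated over all probe sets, and the letters were taken to pair the arrays where every correlation passed 0.1. This held for the temperature comparison in WT (0.44, 0.30 and 0.55 for A, B and C) and in elf3-7 (0.45, 0.34 and 0.62), and at 23 °C for elf3-7 minus WT (0.27, 0.43 and 0.32) and tfl1-1 minus WT (0.62, 0.19 and 0.60). It did not hold for the other comparisons. The replicate C batch can raise these correlations by itself, so they do not show that a letter marks a shared day.

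The alternatives were equal array medians, quantile normalization, leaving out the dimmest 1 of 3 parts of the probe sets, only probe sets naming 1 gene, only the groups compared, a moderated variance with trend and robust fitting, array weights, the replicate letter as a block, and leaving out each array in turn. The batch block and the fit on replicates A and B alone were added after the data had been seen. Overlaps between comparisons used Fisher's exact test, one-sided. The scripts were tested on simulated data with 200 changed probe sets among 22746. In the simulated WT temperature comparison, 20.7% of probe sets changed by 0.5 log2 units, 74.6% of those changed by 1 and 93.0% of those changed by 2 were called. For the difference in response between elf3-7 and WT the shares were 5.17%, 42.4% and 85.5%, and for that between tfl1-1 and WT 6.85%, 42.9% and 84.4%. Seedlings of the same calendar age can differ in developmental stage between temperatures, and stage was not measured here.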

Results

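The study compared seedlings of WT, elf3-7 and tfl1-1 grown at 16 °C and 23 °C, to address how ELF3, a component of the circadian clock, and TFL1, a repressor of flowering in the shoot meristem, act in the response to ambient temperature. Each of the 6 groups had 3 arrays. Correlations between arrays of a group lay between 0.954 and 0.996 over all probe sets, with the lowest value in tfl1-1 at 23 °C. The first principal component held 48.7% of the variance and the second 17.5%. The arrays of replicate C differed from those of A and B in their controls. The 24 Bacillus control probe sets averaged 5.70 ± 0.73 (SD, n = 6) in replicate C and 3.21 ± 0.04 (SD, n = 12) in A and B. The 3′ minus 5′ signal of the actin and GAPDH controls, a measure of RNA or labelling quality, averaged 1.39 ± 0.37 (SD, n = 6) in replicate C and 0.45 ± 0.12 (SD, n = 12) in A and B. Of the 22746 probe sets tested, 5980 differed between replicate C and the others (3099 higher and 2881 lower).

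**Figure D1:**
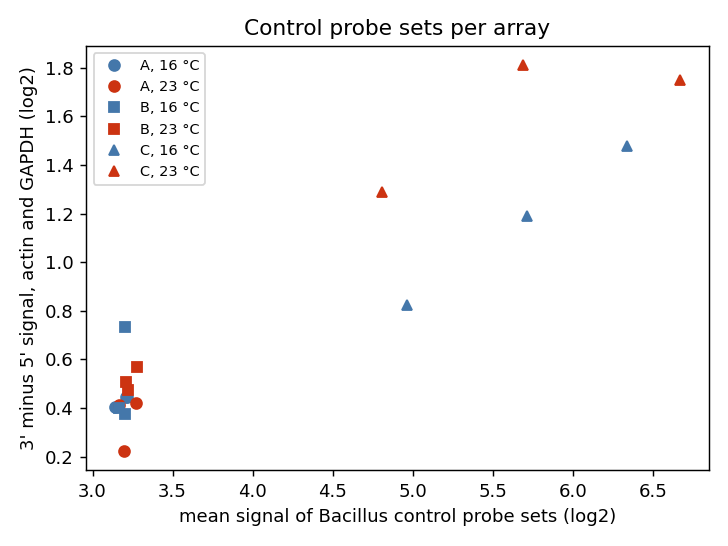
Mean signal of the Bacillus control probe sets (x axis, log2) against the 3′ minus 5′ signal of the actin and GAPDH controls (y axis, log2), 1 point per array, with shape for the replicate and colour for the temperature. The 6 replicate C arrays lie at 4.81 to 6.67 on the x axis and the other 12 at 3.14 to 3.28.

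In WT, the plant defensins PDF1.2 (AT5G44420), a marker of jasmonate and ethylene signalling, and PDF1.2b (AT2G26020) rose at 23 °C. They were the most strongly raised among the genes with a symbol taken by the naming rule. PDF1.2 was 13.8-fold higher (log2 difference 3.79 ± 0.67 SE, n = 3 per group, adjusted p = 0.00681) and PDF1.2b 12.8-fold higher (3.68 ± 0.70, adjusted p = 0.00978). Their sequences are similar, so the arrays may not separate their signals. The cochaperones Fes1A (AT3G09350, 1.52), Hop3 (AT4G12400, 1.40) and SGT1A (AT4G23570, 1.34) rose, while the chaperonin Cpn60beta3 (AT5G56500, -1.49) fell here and in elf3-7 (-1.25). Also higher were RING1 (AT5G10380, 1.59), the cytochrome P450 CYP71B5 (AT3G53280, 1.36) and the glucosyltransferase UGT84A3 (AT4G15490, 1.33). Genes of the mitochondrial genome rose as well, with ccb452 at 2.0 ± 0.31 and nad9, a subunit of respiratory complex I, at 1.55 ± 0.25. Over the 3 genotypes, the 5′ signal of the actin and GAPDH controls was lower at 23 °C by a log2 difference of -0.37 ± 0.10 SE. It was higher in 0 of 9 pairs of same-lettered arrays. Their 3′ signal was lower as well (-0.24 ± 0.06, 2 of 9 pairs higher), and the 25S rRNA control differed by -1.07 ± 0.50.

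Among genes with a symbol, those that fell in WT at 23 °C included the defensin PDF2.5 (AT5G63660, -3.83 ± 0.60), the glutathione transferase GSTU25 (AT1G17180, -3.46 ± 0.57), the subtilase SBT4.12 (AT5G59090, -3.19 ± 0.66) and the cold-induced dehydrin LTI30 (AT3G50970, 8.5-fold lower, -3.09 ± 0.35, adjusted p = 8.15e-04). The tubulin TUB1 (AT1G75780, -2.38), the beta-glucosidase BGLU15 (AT2G44450, -2.32), GSTU26 (AT1G17190, -2.27), TBL39 (AT2G42570, -2.09), GSTU22 (AT1G78340, -2.09) and the thaumatin-like gene ATLP-1 (AT1G18250, -2.08) also fell. The 23 °C means of PDF2.5 (3.70) and GSTU25 (3.78) lay near the Bacillus controls of replicates A and B (3.21), as did the 16 °C mean of Hop3 (3.61), so the sizes of these changes are uncertain. In the cold response list LTI30 fell, and the other 3 measured members, COR15B (AT2G42530, -1.17), COR15A (AT2G42540, -0.87) and COR47 (AT1G20440, -0.84), did not pass the test. The list as a whole was lower (camera in limma, adjusted p = 3.42e-04, median -1.02), with an adjusted p = 0.0517 with an estimated correlation. Of 5 measured flavonoid and anthocyanin genes, 3 fell: the anthocyanin-modifying enzymes AT4G14090 (-1.62), UF3GT (AT5G54060, -1.54) and AT5MAT (AT3G29590, -1.24). DFR (AT5G42800, dihydroflavonol reductase, -1.92, adjusted p = 0.111) and UGT78D2 (AT5G17050, -0.39) did not pass. That list was lower (adjusted p = 1.29e-05, median -1.54; adjusted p = 0.0956 with an estimated correlation). All 4 cold response and all 5 flavonoid genes lay below 0, with medians of -1.005 and -1.64 in replicates A and B and -1.40 and -0.77 in replicate C. With the batch as a block the adjusted p-values were 2.31e-04 and 7.81e-05, and within A and B 1.09e-03 and 2.32e-04.

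Among the remaining lists in WT, ATC (AT2G27550), a relative of TFL1 on the floral repression list, fell (-1.83 ± 0.49, adjusted p = 0.0377), a call lost in each of the 6 fits without 1 array. The 3 root markers, the expansins EXPA18 (AT1G62980, -1.46) and EXPA7 (AT1G12560, -0.98) and the root beta-glucosidase PYK10 (AT3G09260, -0.54), did not pass on their own. As a list they were lower (adjusted p = 0.0406, median -0.98; adjusted p = 0.331 with an estimated correlation). That call held with the batch as a block (adjusted p = 0.0422) and in replicates A and B (0.0232, median -1.20, against -0.58 in C), and was lost with quantile normalization (0.0543), the dim filter (0.0571) and array weights (0.135), and without WT 16 °C A (0.271), WT 23 °C A (0.0548) or WT 23 °C C (0.122). Floral promotion (adjusted p = 0.702, with AGL24 (AT4G24540) at 0.64 and GI (AT1G22770) at -0.48), floral repression (0.680), growth (0.680, EXPA8 (AT2G40610) at 0.44), heat shock (0.354, AT5G48570 at 1.67) and gibberellin (0.680, GID1A (AT3G05120) at 0.62) did not pass. AT5G48570 had WT means of 3.69 ± 0.16 at 16 °C and 5.35 ± 0.06 at 23 °C (SD, n = 3), with no overlap between the arrays. The spread of its test is shared by all groups, and elf3-7 at 23 °C had an SD of 1.44. In WT at 16 °C, AT5G48570 and the other measured members of the list (means 3.41 and 3.45) lay near the Bacillus controls of A and B (3.21). The size of the AT5G48570 rise is thus uncertain, and the list test cannot speak for heat shock genes in general. Of lists with fewer than 3 measured genes, only the jasmonate list had a call in WT, PDF1.2, with JMT (AT1G19640) at 0.15. Values there were 0.66 for AT4G33980 and 0.23 for COR27 (AT5G42900) of the day clock, -0.31 for LHCB4.2 (AT3G08940) of light harvesting, 0.48 for AT2G31790 and -0.29 for BCAT4 (AT3G19710) of glucosinolate synthesis, 0.08 for SAG101 (AT5G14930) of salicylic acid defence, and -0.30 for APL3 (AT4G39210) and -0.21 for DPE1 (AT5G64860) of starch metabolism. Over all lists 6 of 39 genes were called, and 8 when adjusted over these 39 genes alone. No gene of the floral organ, senescence or seed storage lists is named here.

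Over all probe sets, limma called 1549 in WT (644 higher and 905 lower), of which 605 changed at least 2-fold (164 higher and 441 lower). With the batch as a block 3196 were called and with the replicate letter as a block 3157, and all 1549 calls were kept with the batch block. Replicates A and B alone gave 2592 calls, which kept 1234 of the 1549, and 94.8% of these 2592 had the same sign in replicate C. All 20 genes with a symbol named above had the same sign in replicate C, which the naming rule requires. All had a call with the batch block, which leaves the differences unchanged. In A and B 19 had a call, and PDF1.2b had an adjusted p of 0.0652 there. The count was 351 without WT 16 °C B, 369 without WT 16 °C C, 424 without WT 23 °C A and 760 without WT 23 °C B, and of 24 named calls 14, 14, 16 and 18 remained in these fits. The 12 that held without each array were PDF1.2, ccb452, RING1, nad9, SGT1A, PDF2.5, GSTU25, LTI30, BGLU15, TBL39, AT4G14090 and AT5MAT.

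**Figure D2:**
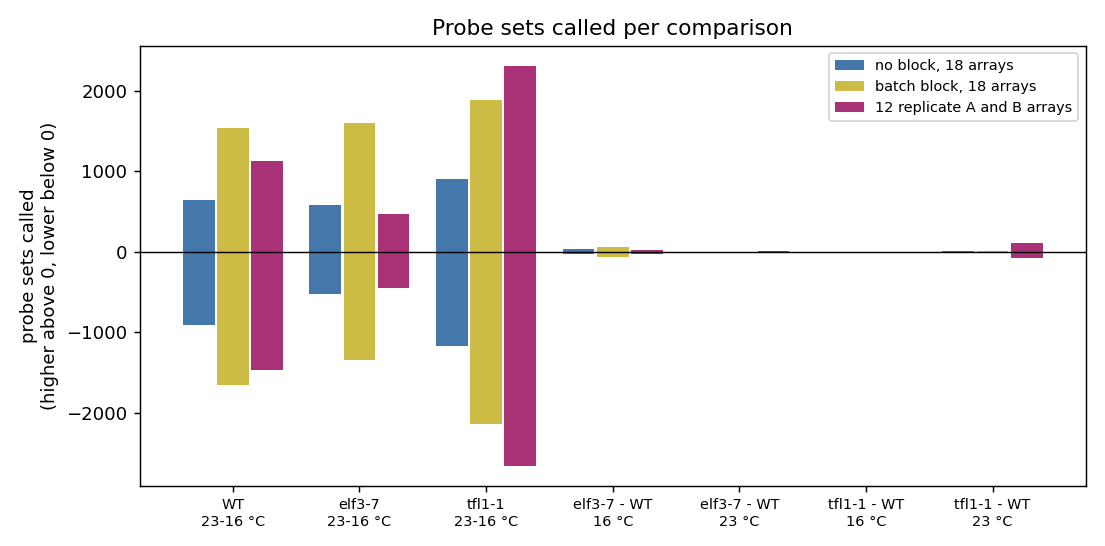
Number of probe sets called (y axis, higher above 0 and lower below 0) in the 7 pairwise comparisons, without a block, with the batch as a block and in replicates A and B alone. Without a block, the temperature comparisons hold 1549, 1107 and 2084 calls and the largest comparison of a mutant with WT 61.

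In elf3-7, genes of anthocyanin synthesis fell at 23 °C. DFR was 10.7-fold lower (log2 difference -3.42 ± 0.69 SE, n = 3 per group, adjusted p = 0.0148), AT4G14090 was at -3.33 ± 0.27 (adjusted p = 2.91e-05), AT5MAT at -2.63 ± 0.20 (adjusted p = 2.66e-05) and UF3GT at -2.52 ± 0.35. So 4 of the 5 measured flavonoid and anthocyanin genes fell, and UGT78D2 was at -0.60 (adjusted p = 0.136). The list was lower (adjusted p = 1.45e-10, median -2.64) and kept its call with an estimated correlation (adjusted p = 0.0280). It was also lower with the batch block (9.22e-09) and in replicates A and B (3.68e-08, median -2.62), and its median in replicate C was -3.16. In the cold response list, LTI30 (-2.11 ± 0.35) and COR15A (-1.90 ± 0.38) fell, and COR15B (-0.53) and COR47 (-0.45) did not pass. That list was lower (adjusted p = 2.07e-03, median -1.22; adjusted p = 0.0527 with an estimated correlation), with 2.09e-03 under the batch block and 1.95e-03 in A and B (median -1.10, against -1.40 in C).

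PDF1.2 (3.39 ± 0.67, adjusted p = 0.0134) and PDF1.2b (2.94 ± 0.70) rose in elf3-7 as well. They were followed by CYP71B26 (AT3G26290, 2.15), the linker histone HIS1-3 (AT2G18050, 1.89), the formate dehydrogenase FDH (AT5G14780, 1.84) and the late embryogenesis protein LEA18 (AT2G35300, 1.74). The glutamate receptor-like GLR2.7 (AT2G29120, 1.66, adjusted p = 2.91e-05), UGT84A3 (1.53), SGT1A (1.48) and Hop3 (1.46, from a mean of 3.33 at 16 °C, near the Bacillus controls) rose too. The 16 °C mean of LEA18 also lay near these controls, so the sizes of the LEA18 and Hop3 rises are uncertain. GSTU25 (-2.80), PDF2.5 (-2.47), the peroxidase Prx37 (AT4G08770, -1.98), BGLU15 (-1.85) and the cell wall glycoprotein HRGP1 (AT3G54590, -1.82) fell. Of heat shock genes, the immunophilin AT5G48570 rose (2.14 ± 0.49, adjusted p = 0.0239), and AT1G53540 (0.34) did not pass, nor did the list (adjusted p = 0.242). At 23 °C AT5G48570 stood at 7.60 in replicate C, against 5.48 in A and 4.84 in B, and its call was lost in 4 settings. Its 16 °C mean (3.83) lay near the Bacillus controls, so the size of its rise is uncertain. APL3, a subunit of ADP-glucose pyrophosphorylase in starch synthesis, fell (-0.97 ± 0.20, adjusted p = 0.0147), with DPE1 at -0.29. Floral promotion (adjusted p = 0.281, AGL24 at 0.68), floral repression (0.331, ATC at -1.40), growth (0.138, EXPA8 at 0.69), gibberellin (0.724, GID1B (AT3G63010) at -0.40, with a median of 0.02 against a test and mean below 0) and root markers (0.148, EXPA18 at -1.41) did not pass. GI was at -0.03. Over all lists 9 of 39 genes were called, and 10 when adjusted over these 39 genes alone.

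The total for elf3-7 was 1107 probe sets (579 higher and 528 lower), of which 403 changed at least 2-fold (211 higher and 192 lower). The calls were 534 higher and 666 lower with equal array medians and 565 higher and 630 lower with quantile normalization, so which direction held more calls depended on the scaling. With the batch as a block 2948 were called, including all 1107, and with the replicate letter as a block 2920. Replicates A and B alone gave 914 calls, which kept 521 of the 1107, and 97.7% of the 914 had the same sign in replicate C. All 20 genes named by symbol had the same sign in replicate C, which the naming rule requires. All had a call with the batch block, which leaves the differences unchanged, and 15 had one in A and B. The other 5 were PDF1.2 (adjusted p = 0.0856 in A and B), PDF1.2b (0.138), LEA18 (0.128, with 1.10 in A and B against 3.0 in C), Hop3 (0.0534) and HRGP1 (0.0583). The count was 363 without elf3-7 16 °C A, 303 without 16 °C B, 209 without 23 °C A and 230 without 23 °C C, and of 23 named calls 13, 10, 8 and 10 remained. Those that held without each array were AT4G14090, AT5MAT, UF3GT, CYP71B26, GLR2.7, LTI30, Prx37 and SGT1A.

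In tfl1-1, PDF1.2 (2.99 ± 0.67 SE, n = 3 per group, adjusted p = 0.0153) and PDF1.2b (2.55 ± 0.70) rose at 23 °C, together with 5 genes of the mitochondrial genome. These were ccb452 (2.72 ± 0.31, 6.60-fold, adjusted p = 3.74e-04), the cytochrome oxidase subunit cox2 (2.64 ± 0.41), and nad9 (2.46 ± 0.25), nad1 (2.25 ± 0.42) and nad5 (2.12 ± 0.36) of complex I. Probe sets for mitochondrial genes can also detect the copy of that genome on nuclear chromosome 2. The isocitrate lyase ICL (AT3G21720), an enzyme of the glyoxylate cycle, rose (2.66 ± 0.62, 6.32-fold, adjusted p = 0.0182), as did Hop3 (2.37) and HIS1-3 (2.25). The 16 °C means of Hop3 (3.38), nad5 (3.64), nad9 (3.76) and cox2 (3.78) lay near the Bacillus controls of A and B (3.21), so the sizes of these rises are uncertain. The mean of the 23 mitochondrial probe sets was 5.40 ± 0.15 (SD, n = 3) at 23 °C and 4.16 ± 0.07 at 16 °C in tfl1-1, against 5.06 ± 0.23 and 4.47 ± 0.09 in WT. In tfl1-1 the 3′ minus 5′ control signal was 0.85 ± 0.85 at 23 °C and 0.54 ± 0.24 at 16 °C, and the 25S rRNA control 6.37 ± 1.51 and 7.47 ± 0.93.

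Cold-induced genes fell in tfl1-1 at 23 °C, LTI30 at -3.46 ± 0.35 (11-fold lower, adjusted p = 1.46e-04), COR15B at -2.68 ± 0.46 and COR15A at -1.97 ± 0.38, and only COR47 (-0.78, adjusted p = 0.181) of the 4 measured did not pass. The list was lower (adjusted p = 7.63e-06, median -2.32), also with an estimated correlation (adjusted p = 0.0117), with the batch block (9.63e-06) and in replicates A and B (3.83e-04, median -2.40; C, -2.17). Of 5 flavonoid and anthocyanin genes 4 fell, DFR (-2.33), UF3GT (-1.43), AT4G14090 (-1.18) and AT5MAT (-0.94), with UGT78D2 at -0.53. The 23 °C mean of AT5MAT (3.75) lay near the Bacillus controls of A and B, so the size of its fall is uncertain. The flavonoid and anthocyanin list was lower (adjusted p = 4.21e-05, median -1.18; adjusted p = 0.141 with an estimated correlation), with 2.02e-04 under the batch block and 4.33e-04 in A and B (median -1.37, against -0.90 in C). GSTU25 (-3.43), SBT4.12 (-2.80), PDF2.5 (-2.76), GSTU26 (-2.45), PDF2.1 (AT2G02120, -2.33), ATLP-1 (-2.32) and TUB1 (-2.30) fell too, several of them less in replicate C than in A and B. The differences in A and B against C were -3.73 and -0.94 for SBT4.12, -3.65 and -0.99 for PDF2.5, -3.10 and -0.80 for PDF2.1, and -3.07 and -0.81 for ATLP-1. AT5G48570 rose (2.0 ± 0.49, adjusted p = 0.0212), with AT1G53540 at 0.93 (adjusted p = 0.0563), and DPE1, an enzyme of starch breakdown, fell (-0.76 ± 0.18). The 16 °C means of AT5G48570 (3.95) and AT1G53540 (3.29) lay near the Bacillus controls of A and B, so the sizes of their differences are uncertain. Root markers did not pass on their own (EXPA18 at -1.57), and were lower as a list (adjusted p = 0.0414, median -1.09; adjusted p = 0.200 with an estimated correlation; 0.0446 with the batch block, and 0.0263 in A and B). That call was lost with the replicate letter as a block (0.0511), quantile normalization (0.0638) and the dim filter (0.0668), and without tfl1-1 16 °C A (0.0727), 23 °C A (0.0825) or 23 °C B (0.0616).

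The remaining lists in tfl1-1 did not pass: floral promotion (adjusted p = 0.237, AGL24 at 0.72), floral repression (0.0582, ATC at -1.58 and SMZ (AT3G54990) at -0.94; under the threshold in 5 other settings, from 0.0343 to 0.0495), growth (0.688, IAA29 (AT4G32280) at 0.62, with a median of -0.05 against a test and mean above 0), heat shock (0.118) and gibberellin (0.529, GID1C (AT5G27320) at 0.51). Over all lists 10 of 39 genes were called, and 17 when adjusted over these 39 genes alone. In total 2084 probe sets were called (906 higher and 1178 lower), 794 of them at least 2-fold (260 higher and 534 lower). With equal array medians the calls were 1127 higher and 1083 lower, and with quantile normalization 906 higher and 1086 lower. The batch block gave 4034 calls, including all 2084, and replicates A and B alone 4970, which kept 1909. Of those 4970, 73.2% had the same sign in replicate C, where differences correlated with those of A and B at 0.39 across probe sets, against 0.74 in WT and 0.74 in elf3-7. The 20 genes named by symbol had the same sign in replicate C, which the naming rule requires. They had a call with the batch block, which leaves the differences unchanged, and 19 had one in A and B. The count was 493, 807 and 1190 without tfl1-1 16 °C A, B and C, and 565, 751 and 4344 without 23 °C A, B and C. Of 26 named calls, 11, 19, 17, 13, 15 and 25 remained in these fits, and ccb452, nad9, nad1, nad5, cox2, Hop3, LTI30, COR15A, COR15B, GSTU25 and GSTU26 kept theirs in all 6.

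Every gene called in both WT and elf3-7 changed in the same direction. The 574 shared probe sets were 287 higher and 287 lower, where independent lists would share 16.4 and 21. WT and tfl1-1 shared 842 (321 higher and 521 lower, 25.7 and 46.9 with independent lists), and elf3-7 and tfl1-1 shared 255 higher, 235 lower and 2 called in opposite directions (23.1 and 27.3). Over the 1549 probe sets called in WT, the difference had the same sign in elf3-7 for 1526 (98.5%) and in tfl1-1 for 1527 (98.6%). The slope of the elf3-7 response on the WT response was 0.735 and that of tfl1-1 0.868. Choosing probe sets by their size in WT pulls such slopes below 1. In a further version, each letter was held out in turn. WT calls and WT sizes came from the WT arrays of the other letters, and the response from the held-out letter. Its slopes were 0.825 ± 0.052 for WT itself, 0.749 ± 0.155 for elf3-7 and 0.821 ± 0.200 for tfl1-1 (SD, n = 3). Calls and WT sizes shared arrays there too, so these slopes are also pulled below 1, that of WT included. In replicates A and B alone the slopes over the WT calls were 0.626 for elf3-7 and 1.06 for tfl1-1. No test was made of the slopes, because probe sets are not independent.

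**Figure D3:**
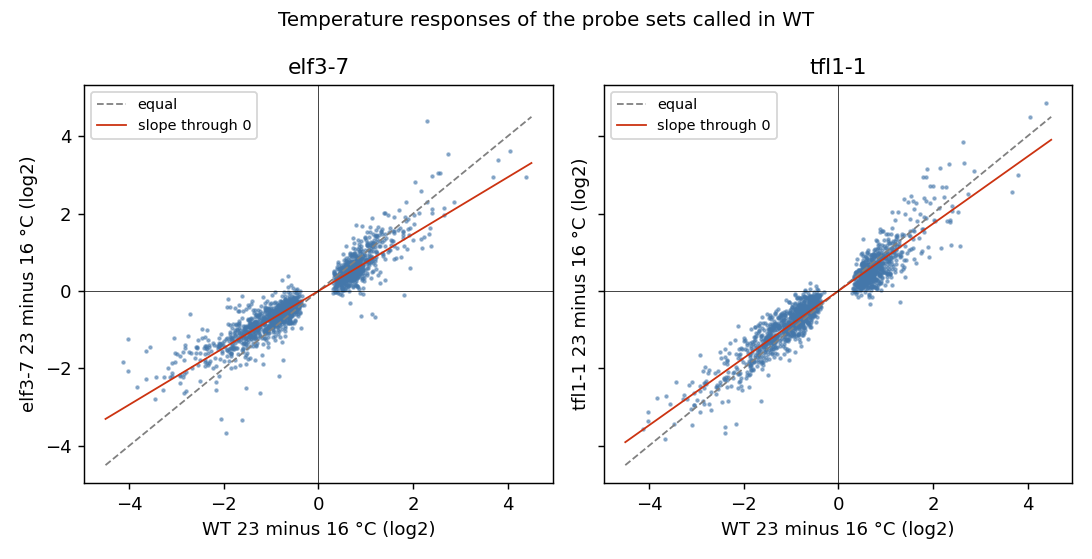
The 23 °C minus 16 °C difference in WT (x axis, log2) against that in elf3-7 (left) and tfl1-1 (right), 1 point per probe set called in WT, with the line of equal change (dashed) and the slope through 0 (solid). The slopes are 0.735 and 0.868.

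At 16 °C, GI (GIGANTEA), a clock and photoperiod gene, was 2.62-fold higher in elf3-7 than in WT (log2 difference 1.39 ± 0.21 SE, n = 3 per group, adjusted p = 0.00748), with means of 9.02 ± 0.08 and 7.63 ± 0.11 (SD, n = 3). Anthocyanin enzymes were also higher in elf3-7, AT4G14090 3.70-fold (1.89 ± 0.27, adjusted p = 0.00748) and AT5MAT 2.68-fold (1.42 ± 0.20, adjusted p = 0.00568). All 5 measured flavonoid and anthocyanin genes lay above WT, though DFR (1.63, adjusted p = 0.680), UF3GT (0.70) and UGT78D2 (0.41) did not pass. The list was higher (adjusted p = 1.07e-08, median 1.42; adjusted p = 0.0538 with an estimated correlation), with 4.01e-07 under the batch block and 2.21e-06 in replicates A and B (median 1.28, against 1.46 in C). The sugar transporter SAG29 (AT5G13170) rose 3.97-fold (1.99 ± 0.26), and LEA18 (-2.85 ± 0.45) and CYP71B26 (-1.30 ± 0.21) fell. The elf3-7 mean of LEA18 (3.87) lay near the Bacillus controls of A and B (3.21), so the size of its fall is uncertain. No other list passed: floral promotion had an adjusted p of 0.175 with GI its only call, floral repression 0.935, growth 0.603, heat shock 0.874, cold response 0.874 (COR15B at -1.06, COR15A at 0.80), gibberellin 0.944 and root markers 0.603. In all 3 of 39 list genes were called, and 5 when adjusted over these 39 genes alone.

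The comparison called 61 probe sets (35 higher and 26 lower), 39 of them at least 2-fold. Only 24 of the 61 name a single gene here, and 5 carry a symbol. The largest difference (3.20 ± 0.41) lay in a probe set with no single gene named here. Several differences larger than that of GI lay in such probe sets or in genes with a locus code only. The batch block gave 126, including all 61, and replicates A and B alone 50, which kept 24, and each of these 50 had the same sign in replicate C. AT4G14090 (1.98) and CYP71B26 (-1.22) were not called in A and B alone. The count was 25, 28 and 18 without WT 16 °C A, B and C, and 28 and 22 without elf3-7 16 °C A and B. Without elf3-7 16 °C B, GI (1.35), AT4G14090 (1.77), LEA18 (-2.96) and CYP71B26 (-1.14) were not called. Without WT 16 °C A that held for GI (1.33) and LEA18 (-2.64), without WT 16 °C C for LEA18 (-2.82) and CYP71B26 (-1.14), without WT 16 °C B for CYP71B26 (-1.32) and without elf3-7 16 °C A for LEA18 (-2.67). AT5MAT and SAG29 kept their calls without each array, and lost them with only the groups compared (adjusted p = 0.0547 and 0.0716), as did CYP71B26 (0.0852).

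At 23 °C, GI was 3.59-fold higher in elf3-7 than in WT (1.84 ± 0.21 SE, n = 3 per group, adjusted p = 0.0026), with means of 9.0 ± 0.10 and 7.15 ± 0.45 (SD, n = 3). GI was the only higher call. AT1G43590 (5.06-fold lower, -2.34 ± 0.21, adjusted p = 4.34e-04) and AT5G44520 (-0.78 ± 0.12) fell, together with 4 probe sets unnamed here. All 7 were also called at 16 °C in the same direction, where AT1G43590 was at -1.34 and AT5G44520 at -0.64. GI was called with the batch block (adjusted p = 5.40e-04), in replicates A and B (1.61, adjusted p = 0.0311) and without each array in turn, and its difference in replicate C was 2.32. It was not called with only the groups compared (adjusted p = 0.305). Among the floral promotion genes only GI was called, with FD (AT4G35900) at -0.17, AGL42 (AT5G62165) at 0.16 and AGL24 at 0.14. Floral promotion was higher as a list (adjusted p = 0.0422, median 0.15; adjusted p = 0.121 with an estimated correlation), and the list was not tested without GI. That call was lost with the batch block (adjusted p = 0.0695), in A and B (0.0546; median 0.26, and 0.06 in C) with the replicate letter as a block (0.0679), with only the groups compared (0.113) and with array weights (0.131), and without WT 23 °C A (0.0629), WT 23 °C B (0.0561), elf3-7 23 °C B (0.1) or elf3-7 23 °C C (0.0821).

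The other lists did not pass at 23 °C in elf3-7: floral repression (adjusted p = 0.684, mean 0.01 against a median and test below 0), growth (0.658), heat shock (0.662), cold response (0.662, LTI30 at 0.82), flavonoid and anthocyanin (0.684, UF3GT at -0.27), gibberellin (0.348) and root markers (0.120, EXPA18 at 0.76). Of 39 list genes 1 was called, and 1 when adjusted over these 39 genes alone. The 7 calls of limma compare with 1177 probe sets at an unadjusted p under 0.05, 11 calls with the batch block (all 7 included) and 17 in replicates A and B alone, which kept 4. Of these 17, 76.5% had the same sign in replicate C. Without elf3-7 23 °C B the count was 3.

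**Figure D4:**
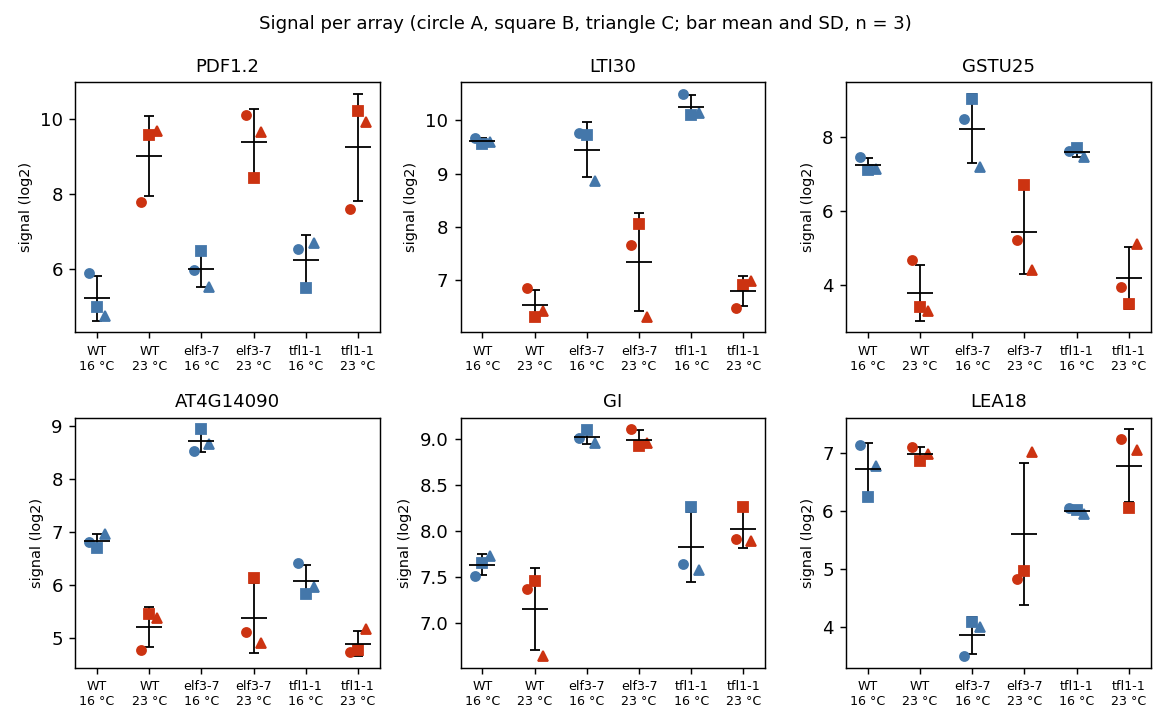
Log2 signal of PDF1.2, LTI30, GSTU25, AT4G14090, GI and LEA18 in the 6 groups (y axis), with 1 point per array (circle A, square B, triangle C) and the mean and SD as bars. GI lies at 9.02 and 9.0 in elf3-7 and at 7.63 and 7.15 in WT at 16 °C and 23 °C.

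At 16 °C no probe set differed between tfl1-1 and WT by limma, against 1717 at an unadjusted p under 0.05. The count was also 0 with the batch block, with the replicate letter as a block, in replicates A and B alone, with only the groups compared and without each array. It was 1 with equal medians, quantile normalization, the dim filter, only probe sets naming 1 gene, and trend and robust moderation, and 336 with array weights. SAT32 (AT1G27760), a gene named for salt tolerance, was at -2.08 (adjusted p = 0.0759), and GI at 0.20. The 4 cold response genes all lay above WT (COR15B at 1.41 and COR15A at 1.32, none called), and the list was higher (adjusted p = 3.00e-04, median 0.98), also with an estimated correlation (adjusted p = 0.0383), with the batch block (2.96e-04) and in replicates A and B (1.04e-05, median 1.18, against 0.58 in C). The 5 flavonoid and anthocyanin genes all lay below WT (DFR at -0.97 and AT5MAT at -0.78, none called), and that list was lower (adjusted p = 3.47e-03, median -0.76; adjusted p = 0.392 with an estimated correlation), with 9.41e-03 under the batch block and 9.61e-03 in A and B (median -0.85, against -0.64 in C), a call lost without tfl1-1 16 °C B (0.0628).

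Floral promotion (adjusted p = 0.402), floral repression (0.402, SNZ (AT2G39250) at 0.40), growth (0.487, EXPA8 at 0.67), heat shock (0.967, mean 0.01 against a median and test below 0), gibberellin (0.192, GID1A at 0.47) and root markers (0.570) did not pass at 16 °C in tfl1-1. The gibberellin list passed with the batch block (0.0355) and in A and B (3.48e-04). None of 39 list genes was called, nor when adjusted over these 39 genes alone (0 in both).

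At 23 °C, SAT32 was 5.52-fold lower in tfl1-1 than in WT (-2.47 ± 0.29 SE, n = 3 per group, adjusted p = 0.00979), with means of 5.27 ± 0.63 and 7.74 ± 0.37 (SD, n = 3). It was called with the batch block (adjusted p = 0.0139) and in replicates A and B (-2.97, adjusted p = 0.00548), its difference in replicate C was -1.46, and its call was lost without tfl1-1 23 °C B (-2.17) and with only the groups compared (adjusted p = 0.966). AT1G43590 (-1.41 ± 0.21) and AT4G28080 (-0.61 ± 0.09) fell and AT1G73480 rose (1.41 ± 0.20), with 4 further higher probe sets unnamed here. GI was at 0.87 ± 0.21, which did not pass over all probe sets (adjusted p = 0.231). When adjusted over the 39 list genes alone, GI was the 1 gene called, against 0 over all. No list passed, with adjusted p-values of 0.0844 for floral promotion, 0.364 for floral repression (SMZ at -0.75), 0.532 for growth (IAA29 at 0.72), 0.471 for heat shock, 0.323 for cold response, 0.0552 for flavonoid and anthocyanin (DFR at -1.39), 0.188 for gibberellin (GID1C at 0.67) and 0.633 for root markers.

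The tfl1-1 comparison at 23 °C called 8 probe sets (5 higher and 3 lower), and 1924 had an unadjusted p under 0.05. With equal array medians the split was 5 higher and 6 lower. The batch block gave 32 calls and the replicate letter as a block 29, and all 8 were kept with the batch block. Replicates A and B alone gave 193 calls, which kept 7, and 54.9% of these 193 had the same sign in replicate C, where differences correlated with those of A and B at 0.01 across probe sets. The count was 745 without tfl1-1 23 °C C, 0 without tfl1-1 23 °C B, and 14, 3 and 4 without WT 23 °C A, B and C.

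The calls of the 2 mutants against WT shared AT1G43590, which was lower in both at 23 °C, and nothing at 16 °C. These comparisons use the same WT arrays. With no effect at all, simulated groups gave a correlation of 0.499 and a covariance of 0.029 between the differences at 23 °C, and the observed values were -0.043 and -0.0028. At 16 °C the simulated values were 0.498 and 0.029 and the observed ones -0.064 and -0.0043. The simulated noise was independent between arrays. Its spread included the replicate C batch, which cancels in the differences between real groups. The simulated covariance may thus be too high, and no conclusion is drawn from the gap to the observed values. The controls were not split, and part of any excess in shared calls may come from the shared controls.

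The temperature response itself was then compared between each mutant and WT. The anthocyanin genes AT4G14090 (-1.70) and AT5MAT (-1.39) had larger measured falls at 23 °C in elf3-7 than in WT. These differences were called only when adjusted over the 39 genes of all lists alone (2 of 39), against 0 over all probe sets. In elf3-7 and WT, the 23 °C means were 5.38 and 5.19 for AT4G14090 and 4.26 and 4.23 for AT5MAT. At 16 °C they were 8.71 and 6.82, and 6.90 and 5.47. The result thus largely repeats the difference between elf3-7 and WT at 16 °C, from the same arrays. All 5 flavonoid and anthocyanin genes lay below 0 in this comparison, and the list was lower (adjusted p = 1.13e-07, median -1.39; adjusted p = 0.0797 with an estimated correlation). It was lower with the batch block (1.57e-06) and in replicates A and B (1.73e-03, median -0.69), with a median of -2.17 in replicate C. The other lists did not pass: floral promotion (adjusted p = 0.404), floral repression (0.674), growth (0.247), heat shock (0.845), cold response (0.404), gibberellin (0.404) and root markers (0.460). For elf3-7 limma called 0 probe sets, with 542 at an unadjusted p under 0.05. The count was 0 under every other setting and left-out array, except for 2 without elf3-7 23 °C A.

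For the response of tfl1-1 against that of WT, limma called 0 probe sets, with 821 at an unadjusted p under 0.05. The counts were 2 with the replicate letter as a block, 1 with the batch block, 0 in replicates A and B alone, 23 with array weights and 13 without tfl1-1 23 °C C, and 0 under the other settings. None of 39 list genes was called, nor when adjusted over these 39 genes alone. The lists had adjusted p-values of 0.605 for floral promotion, 0.168 for floral repression, 0.917 for growth, 0.765 for heat shock, 0.109 for cold response, 0.765 for flavonoid and anthocyanin, 0.917 for gibberellin (median and mean -0.04 against a test above 0) and 0.917 for root markers. Across probe sets, the differences in response in replicate C correlated with those in A and B at 0.04 for elf3-7 and 0.003 for tfl1-1.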

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

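Of the tests in this part, those by other splits of the arrays were planned before the files were seen, and the 3 tests of the mitochondrial genes were chosen after the results had been seen, as was the comparison of the replicate C controls.

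The Bacillus control probe sets lie outside the gene measurements, and their mean signal was higher by 2.493 log2 units in replicate C than in A and B, the lowest replicate C array lying 1.53 above the highest A or B array. Such transcripts are spiked in during labelling, and the labels do not state a separate batch for replicate C. This gap is what raised the idea of a labelling batch, so it is no independent test of it. The probe sets of the plastid genome (0.60 ± 0.12 SE, higher in 6 of 6 groups) and of 25S rRNA (1.55 ± 0.63, higher in 5 of 6) were brighter in replicate C. No biological explanation was tested, since the labels give no biological difference between the letters.

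Some gene lists passed the test of a difference between a mutant and WT in the response to temperature. In elf3-7 these were the flavonoid and anthocyanin genes, lower with an adjusted p = 1.13e-07 (0.0797 with an estimated correlation), and the genes of the chromosome 2 copy of the mitochondrial genome, lower with an adjusted p = 0.0471 (0.889 with an estimated correlation). In tfl1-1 they were the mitochondrial genome (adjusted p = 1.96e-06, and 0.423 with an estimated correlation), the plastid genome (6.81e-06, and 0.820) and the chromosome 2 copy (0.000596, and 0.820), all higher. The flavonoid and anthocyanin list was chosen before the data were examined. The mitochondrial, plastid and chromosome 2 copy lists are among the gene families picked after the first results had been seen. Probe sets for mitochondrial genes can also detect the chromosome 2 copy. The mitochondrial and chromosome 2 copy lists may thus not be separate evidence. The tests were of the difference between the responses itself. Within replicates A and B the adjusted p-values were 1.73e-03 and 0.0415 for the elf3-7 lists in this order, and 2.53e-06, 0.0132 and 2.23e-04 for the tfl1-1 lists. With the batch as a block they were 1.57e-06 and 0.0575, and 9.65e-07, 3.15e-07 and 2.81e-04. The median of the plastid list was 0.14 in A and B and 0.68 in replicate C, that of the mitochondrial list 0.72 and 1.15, and that of the flavonoid list -0.69 and -2.17.

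Arrays were matched by letter here, also in tfl1-1, where the letters did not meet the rule for pairing. The 23 mitochondrial probe sets were brighter at 23 °C by 0.72 ± 0.15 (SE over 9 pairs), in 9 of 9 pairs of arrays. With 3′ bias of the labelled RNA as the explanation they should also be brighter in replicate C, where their shift was 0.162 ± 0.154, a value that cannot tell. With more 3′ bias in the 23 °C arrays the 3′ minus 5′ control signal should be higher at 23 °C, where it differed by 0.129 ± 0.121, which cannot tell either. With carry-over of organelle and ribosomal RNA into the labelling the plastid set should be brighter at 23 °C as well. Over the 3 genotypes it differed by -0.0263 ± 0.103. Its means at 16 °C and 23 °C were 10.63 and 10.45 in WT, 10.48 and 10.42 in elf3-7, and 10.41 and 10.57 in tfl1-1. The pooled value speaks against carry-over only if plastid transcripts do not themselves change with temperature, which was not tested. A biological effect of temperature may remain, though stage was not measured. The actin and GAPDH signal was lower at 23 °C at the 5′ end (-0.37 ± 0.10) and at the 3′ end (-0.24 ± 0.06).

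Whether a chance division of the arrays gives as many calls was tested by splitting the 6 arrays of each comparison into 3 and 3 in all 10 ways, where the share cannot fall under 0.1. For WT, elf3-7 and tfl1-1 between temperatures, 1 of 10 splits, the real one, gave as many calls in each (1549, 1107 and 2084), and the highest other counts were 0, 1 and 0. For elf3-7 minus WT, 1 of 10 did so at 16 °C (61, highest other 21) and 1 of 10 at 23 °C (7, highest other 1). For tfl1-1 minus WT at 16 °C, 10 of 10 splits gave 0. With a real count of 0 no split could give fewer. Since 10 splits cannot bring the share under 0.1, the test cannot exclude chance in any of the pairwise comparisons. Every other split also puts arrays of both groups on each side. Where the groups differ this widens the spread, so low counts in the other splits do not exclude chance either. For tfl1-1 minus WT at 23 °C, 2 of 10 gave 8 or more, and the highest other count was 3046, with WT A, tfl1-1 A and tfl1-1 B against WT B, WT C and tfl1-1 C. That split keeps both A arrays on one side and both C arrays on the other, and points to structure among these samples apart from genotype. Letters pair the arrays in this comparison by the rule given above, which the replicate C batch can help to meet. Among the 4 splits that part all pairs, the highest count other than the real 8 was 0. The count with the batch as a block was 32, and within A and B 193. For the differences in response, 100 of 100 regroupings gave at least the real count of 0 for elf3-7, and 100 of 100 for tfl1-1, with highest counts of 204 and 2721. With a real count of 0 this outcome was certain beforehand, so it says nothing about a chance division.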

How the results depend on the processing

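The results are grouped by setting. No call of a named gene or of a fixed list turned to the opposite direction. The balance of higher and lower calls did turn with equal array medians, from 579 higher and 528 lower to 534 and 666 in elf3-7 between temperatures, from 906 and 1178 to 1127 and 1083 in tfl1-1 between temperatures, and from 5 and 3 to 5 and 6 for tfl1-1 minus WT at 23 °C. It turned in elf3-7 with quantile normalization too (565 and 630); the cause was not tested. Of 88 named gene results, 36 kept their side of the threshold in every setting, as did 45 of 72 tests of fixed lists. Single settings left 1220 of 1420 named gene values and 1224 of 1293 list values on the same side. Most losses among named genes came from leaving out 1 array (164), from fitting only the groups compared (24) and from replicates A and B alone (9). The number of arrays limits precision, and dim transcripts cannot be told from background with these values.

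With only probe sets naming 1 gene, which tests fewer probe sets, counts were 745 in WT, 545 in elf3-7 and 1069 in tfl1-1 between temperatures, 15 and 2 for elf3-7 minus WT at 16 °C and 23 °C, and 1 and 4 for tfl1-1 minus WT. Shared calls in that setting were 261 for WT and elf3-7, 403 for WT and tfl1-1, 241 for elf3-7 and tfl1-1, 2 for elf3-7 minus WT at both temperatures and 1 for tfl1-1 minus WT at both temperatures. The count for tfl1-1 minus WT at 16 °C rose from 0 to 1 with equal medians, 1 with quantile normalization, 1 with the dimmest probe sets left out and 1 with trend and robust moderation, and shared calls of tfl1-1 minus WT at both temperatures to 1 in the first 3 of these; the cause was not tested.

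With only the groups compared, which leaves fewer arrays to estimate the spread, the counts were 964, 599 and 791 for WT, elf3-7 and tfl1-1 between temperatures, 21 and 1 for elf3-7 minus WT at 16 °C and 23 °C, and 0 for tfl1-1 minus WT at 23 °C. With array weights they were 3546, 4419 and 7100 between temperatures, 537 for elf3-7 minus WT at 16 °C, 336 and 1593 for tfl1-1 minus WT, and 23 for the tfl1-1 difference in response; the cause was not tested.

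With the replicate letter as a block, the counts were 3157, 2920 and 4012 between temperatures, 120 for elf3-7 minus WT at 16 °C, 29 for tfl1-1 minus WT at 23 °C and 2 for the tfl1-1 difference in response. Of 18 arrays, 14 correlated best with an array of their own letter. The replicate C batch can give such matches by itself, so this cannot tell whether letters mark shared conditions. The letter block ended the calls of root markers in tfl1-1 (0.0511) and of floral promotion for elf3-7 minus WT at 23 °C (0.0679), and gibberellin passed for tfl1-1 minus WT at 16 °C (0.0436). It changed no other call named here. The batch alternatives were chosen after the data had been seen. With the batch as a block the counts were 3196, 2948 and 4034 between temperatures, 126 and 11 for elf3-7 minus WT, 32 for tfl1-1 minus WT at 23 °C and 1 for the tfl1-1 difference in response. In replicates A and B alone they were 2592 in WT and 4970 in tfl1-1 between temperatures, 17 for elf3-7 minus WT at 23 °C and 193 for tfl1-1 minus WT at 23 °C; the cause was not tested. In A and B alone, gibberellin passed in WT (0.0232), tfl1-1 (0.0489), elf3-7 minus WT at 23 °C (2.77e-03), tfl1-1 minus WT at 16 °C (3.48e-04) and the elf3-7 difference in response (1.14e-04), root markers in elf3-7 (0.0443) and floral repression in tfl1-1 (0.0392).

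An estimated correlation between the genes of a list kept 3 of the 13 fixed list calls: flavonoid and anthocyanin genes in elf3-7 between temperatures, and cold response genes in tfl1-1 between temperatures and for tfl1-1 minus WT at 16 °C. The other settings that ended a fixed list call are given with the results.

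Some fixed lists passed only in other settings; the cause was not tested. With equal medians these were floral repression in tfl1-1 between temperatures (0.0361), flavonoid and anthocyanin genes for tfl1-1 minus WT at 23 °C (0.0243) and cold response in the tfl1-1 difference in response (0.0495). For tfl1-1 minus WT at 23 °C, flavonoid and anthocyanin genes passed with quantile normalization (0.0234), the dim filter (0.0154) and array weights (0.00669), and floral promotion with quantile normalization (0.0343). Array weights also passed floral repression in tfl1-1 (0.0495) and gibberellin for tfl1-1 minus WT at 16 °C (0.0349), which the batch block passed too (0.0355). With only the groups compared, growth passed in elf3-7 (0.0463) and in its difference in response (0.0332), floral repression (0.0343) and heat shock (0.0343) in tfl1-1, root markers for elf3-7 minus WT at 23 °C (0.0193) and gibberellin for tfl1-1 minus WT at 16 °C (0.0397). Leaving out 1 array let 13 list tests pass, with adjusted p-values from 0.0022 to 0.0485.

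Leaving out 1 array left 2 in its group. Counts then ran from 351 to 1405 in WT, 209 to 1612 in elf3-7 and 493 to 4344 in tfl1-1 between temperatures. They ran from 18 to 65 and 3 to 6 for elf3-7 minus WT at 16 °C and 23 °C, from 0 to 0 and 0 to 745 for tfl1-1 minus WT, and from 0 to 2 and 0 to 13 for the differences in response of elf3-7 and tfl1-1. Slopes ran from 0.681 to 0.738 for elf3-7 and from 0.762 to 0.873 for tfl1-1. Counts both fell and rose with fewer arrays; the cause was not tested. GI for tfl1-1 minus WT at 23 °C passed without tfl1-1 23 °C C (log2 difference 0.94, adjusted p = 0.0445).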

Other observations

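Genes of cell division were lower as a list at 23 °C in each genotype. This part uses the 20 gene families chosen after the annotation and the first results had been seen, and no call among them held with an estimated correlation. In WT, 9 of 26 measured cell division genes fell, among them KINESIN-12B (AT3G23670, -1.68 ± 0.33 SE, n = 3 per group) and the mitotic kinases AUR1 (AT4G32830, -1.59) and AUR2 (AT2G25880, -1.44), and the list was lower (adjusted p = 3.23e-09, median -0.57; 1.71e-09 with the batch block and 1.07e-09 in replicates A and B). In elf3-7, 3 fell (adjusted p = 3.10e-06), none of them called in replicates A and B alone, and in tfl1-1 6 fell and PSF2 rose (adjusted p = 9.63e-07). The tfl1-1 median was -0.59 in A and B and -0.16 in replicate C, where PSF2 was at -0.01 (1.03 in A and B) and 3xHMG-box2 at -0.27 (-2.67 in A and B). Histone H2B genes were lower in WT (adjusted p = 1.63e-03, HTB1 and HTB11 called), elf3-7 (0.0459) and tfl1-1 (6.95e-03). The same held for expansins and xyloglucan endotransglucosylases (4.65e-03, 0.0445 and 2.60e-03; XTH19 at -1.41 in WT, though EXGT-A3 rose in WT, at 1.17, and in elf3-7, at 1.31) and trichome birefringence-like genes (0.0246, 0.0445 and 2.60e-03). CYP71B genes were higher in WT (8.50e-03), elf3-7 (0.0445) and tfl1-1 (8.56e-03). In replicates A and B alone, histone H2B (0.207), CYP71B (0.109) and trichome birefringence-like genes (0.0690) did not pass in elf3-7.

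Tau glutathione transferases were lower at 23 °C in WT (adjusted p = 8.93e-03, 4 of 11 called) and tfl1-1 (2.60e-03, 5 of 11 called, GSTU20 at -1.87). In elf3-7 the list did not pass (0.0628), with GSTU25 (-2.80) and GSTU22 (-1.77) called. Mitochondrial genes were higher in WT (4.65e-03, 3 of 16 called) and tfl1-1 (6.43e-08, 8 of 16 called, cox1 at 1.73), as were the genes of the chromosome 2 copy (4.65e-03 and 1.76e-07). In elf3-7 these 2 lists did not pass (0.0944 and 0.393), though ccb452 (1.33), nad9 (1.29), AT2G07707 (1.86) and AT2G07718 (1.29) rose. The plastid genome was lower in WT (0.0131; 0.0645 in replicates A and B). Tubulin (9.87e-03), glycosyl hydrolase 9 (0.0485) and serine carboxypeptidase-like genes (0.0332) were lower and chaperones (0.0322; 0.337 in A and B) higher in tfl1-1, and Cpn60beta3 of the chaperone list fell in WT (-1.49) and elf3-7 (-1.25). These lists did not pass in WT or elf3-7, the difference between tfl1-1 and WT in their response did not pass either, and single members also changed there, such as TUB1 (-2.38) and GH9B13 (-1.56) in WT.

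Between genotypes, all 9 measured ATG8 autophagy genes lay above WT in tfl1-1 at 16 °C (adjusted p = 4.16e-05, median 0.44) and at 23 °C (1.57e-07, median 0.63), and none was called on its own. At 23 °C the median was 0.72 in replicates A and B and -0.02 in replicate C. At 16 °C in tfl1-1, cell division (1.39e-04), mitochondrial (0.0316), plastid (0.0316) and chromosome 2 copy genes (4.38e-05) were lower and UDP-glycosyltransferases higher (0.0424; median 0.02, and -0.0018 with equal array medians). At 23 °C in tfl1-1, mitochondrial (1.92e-03) and plastid genes (9.23e-03) were higher and serine carboxypeptidase-like genes lower (0.0126). In elf3-7, plastid genes were lower at 16 °C (5.86e-03). At 23 °C in elf3-7, histone H2B (0.0349), expansins and xyloglucan endotransglucosylases (0.0199; median 0.27 in A and B and -0.04 in C) and tau glutathione transferases (0.0349) were higher. Beta-glucosidases (lowest adjusted p 0.142), SWEET sugar transporters (0.412), plant defensins and thionins (0.0701) and ubiquitin genes (0.0614) passed in no comparison.

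SAT32 had means of 5.37 ± 0.38 at 16 °C and 5.27 ± 0.63 at 23 °C in tfl1-1 (SD, n = 3). Its means were 7.45 ± 0.12 and 7.74 ± 0.37 in WT and 7.52 ± 0.24 and 7.59 ± 0.37 in elf3-7. All 6 tfl1-1 arrays, at 5.92 or less, lay below all 12 others, at 7.25 or more.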
